A study of Curcuma longa with 24 samples.

How the data were processed

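Turmeric RNA of 10 groups was measured on 24 custom Agilent 2-colour arrays, with one group in Cy3 and another in Cy5. The groups were rhizome at 3, 5 and 7 months and leaf and root at 7 months, each for the varieties FMO and TYA. Per the labels, the plants grew in a greenhouse, RNA was extracted with a plant RNA kit and amplified with amino-allyl labelling, and the arrays form 2 loops, one of rhizome stages and one of organs, joined at the 7-month rhizomes. Each array carries 15208 probes of up to 60 bases (15182 distinct sequences) and 536 control spots. The product descriptions, 6771 distinct ones, come with the files; 2303 probes are described as unknown. The sources used here give no genome build or coordinates for the probes, and the list of reference genes at hand could not be matched to them.

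Per the file headers, the scanner software was Feature Extraction 9.5.3.1, and the mean and background signals of both channels are in unit intensity, without normalization. The processed signals, per the file headers also intensity, had been background-subtracted, detrended and dye-normalized (linear and lowess), with dim signals replaced by surrogates. The log ratios are log10 of Cy5 over Cy3 per the file headers, and the deposited value table holds the same log10 ratios (largest difference 0). The columns of unit other are spot marks per the file headers: outlier, saturation and well above background.

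Signals were corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3, and expressed as log2 of Cy5 over Cy3. Spots marked as non-uniform outliers were left out on their array. Probes were kept where they were well above background in at least 3 of the 46 channels, which kept 14315 and removed 893. Of those kept, 9194 have a product description, 5121 have none, and 757 have a name that ends in _as. One limma model over 23 arrays fitted all groups with a dye term common to all arrays, which left 13 residual degrees of freedom; standard errors are those of the fit, moderated by eBayes. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and counts with an absolute log2 fold change of at least 1 are given too. Its p-values are 2-sided. The labels give no plant or extract numbers, so there was no block or pairing. The array labelled TYA root in both channels was left out, since as labelled it carries no contrast. Organ and stage comparisons are means over both varieties, the rhizome variety comparison is the mean over 3 stages, and the variety interactions are contrasts of the same model.

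Gene lists, 18 in number, were written before the data were examined, as were the comparisons, the filter, the alternatives and the rule for named genes. List members were matched by product description, each probe being a member, and lists of at least 5 members were tested with camera (preset correlation 0.01) on values that keep the marked spots, adjusted over lists and comparisons. camera with an estimated correlation and fry were run beside it. The polyketide list matched chalcone synthase descriptions alone, the phenylpropanoid list also prolyl 4-hydroxylases, the isoprenoid list also a tRNA isopentenyltransferase, the P450 list also reductases, the photosynthesis list also plastocyanin-like domain proteins and chaperonins, the cell division list also FtsH proteases, and the heat shock and drought list also metallothioneins. The rule for named genes took, per comparison, among called probes with a product description and an absolute log2 fold change of at least 1, the 8 highest and the 8 lowest, 1 probe per description. It added the 2 members of each list with the smallest adjusted p in each direction and at most 10 polyketide synthases. The text names a selection of the genes so chosen. Where a probe was above background in none of the channels of a side, its fold is given as a lower bound.

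The arrays were scanned in 3 sets of 8, and scan was taken as a possible batch: values within scans and with scan as a fixed block stand beside the results. Scan 1 held rhizome arrays alone, and roots of FMO and of TYA were in different scans. The median share of outlier spots was 5.27% (range 0.723% to 20.6%). Each array's ratios were compared with those predicted from a fit without it; r across probes ranged from -0.0919 to 0.852 and was above 0 for 22 of 23 arrays. The 2 arrays that pair the 7-month rhizomes of both varieties with opposite dyes had an r across probes of -0.384, and of -0.70 with the dye term removed.

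The model was tested on simulated data with the same design, missing spots and spread, in which 50 probes per comparison were changed by a given log2 size. Of 50 changed by log2 1 and by log2 2, the calls recovered were: leaf minus rhizome 28 and 36 (14160 probes tested), root minus rhizome 30 and 39 (14196), leaf minus root 26 and 45 (14147), rhizome 5 minus 3 months 31 and 42 (13805), 7 minus 5 months 33 and 35 (13977), 7 minus 3 months 29 and 35 (13820), rhizome FMO minus TYA 27 and 46 (13798), leaf FMO minus TYA 19 and 34 (14190), root FMO minus TYA 20 and 31 (14182), variety by stage 17 and 31 (13842), variety by leaf 14 and 31 (14163), and variety by root 11 and 24 (14182). Between 1 and 8 unchanged probes were called per comparison.

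The alternatives were: no background correction, scanner-processed signals, median centring, Aquantile between arrays, no filter, a filter of probes well above background in both channels of many arrays (10280 probes), no dye term, scan as a fixed or a random block, rhizome-only arrays or arrays with leaf or root alone, the array labelled TYA root in both channels added, the ratio of the TYA with FMO rhizome array at 7 months turned or that array left out, eBayes with trend and robust, arrayWeights, the deposited log ratios, each of 23 arrays left out, and for lists camera with an estimated correlation. Added after the data were examined were: leaving out 2 arrays, the one with the most outlier spots and the one with the lowest predicted correlation; leaving out probes whose name ends in _as; 1 probe per description; and comparing leaf and root through different rhizome channels.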

Results

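Gene expression was measured in turmeric (Curcuma longa), a plant of the ginger family grown for its rhizome, in 2 varieties, Fat Mild Orange (FMO) and Thin Yellow Aromatic (TYA). RNA came from greenhouse plants, from the rhizome at 3, 5 and 7 months and from leaf and root at 7 months, which gave 10 RNA groups. The groups were hybridised in pairs, one in Cy3 and the other in Cy5, to 24 Agilent 2-colour arrays of turmeric probes. The 23 arrays whose labels name a different group in each channel entered the comparisons, and the array labelled TYA root in both channels did not. Each 7-month rhizome group was in 8 (FMO) or 7 (TYA) channels, TYA root was in 3, and every other group was in 4. The median Cy3 signal of an array ranged from 92.52 to 445 and the median Cy5 signal from 55.2 to 342.1. In Cy3, 66.5% to 93.6% of probes were well above background, and in Cy5 53.2% to 87.7%. A gene is identified by its probe and by the product description of the file, which rests on similarity to a protein of another species. Values in parentheses after a probe name are log2 fold changes with their standard error from the limma fit, and rose or fell refers to an adjusted p under 0.05. After a list's counts, those adjusted over the list alone are given where they differ. The labels do not say whether arrays of a group shared a plant or an RNA extract, so the p-values measure the spread between arrays, which may be technical.

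The first comparison asked which transcripts set the leaf apart from the rhizome at 7 months, with 8 leaf and 15 rhizome channels and the mean of both varieties. Photosynthesis transcripts were among the highest in leaf. They included the chloroplast ATP synthase gamma chain (pGT1_01304_01, 8.52 ± 0.36), the 23-kDa protein of the oxygen-evolving complex of photosystem II (pGT1_06624_01, 8.38 ± 0.44), a photosystem II psbY protein (pGT1_02783_01, 8.27 ± 0.61) and the chlorophyll a-b binding proteins CAB-8 (pGT1_00013_08, 7.90 ± 0.28) and CP24 (pGT1_03445_01, 7.86 ± 0.55). Serine-glyoxylate aminotransferase, an enzyme of photorespiration, rose as far (pGT1_05984_01, 7.84 ± 0.41). Among the lowest in leaf, that is the highest in rhizome, were the sugar-binding storage and defence proteins lectin GNA-1 (pGT1_00230_01, -7.48 ± 0.89) and agglutinin (pGT1_02245_01, -7.42 ± 0.94) and an aspartic proteinase (pGT1_04512_01, -6.48 ± 0.73). Also lower were the knotted-like homeobox protein KNAP3 (pGT1_00152_04, -5.95 ± 0.97), sucrose synthase (pGT1_06131_02, -5.86 ± 0.89) and a type-2 metallothionein (pGT1_05035_01, -5.72 ± 0.44). The lectin and agglutinin spots were saturated in 11 and 12 of the 15 rhizome channels, and the ATP synthase spot in 5 of the 8 leaf channels, so these ratios are compressed.

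Of the gene lists, photosynthesis was higher in leaf: 77 of 161 rose and 11 fell (list alone 84 and 11, camera adjusted p = 2.22e-16, and adjusted p = 0.128 with an estimated correlation). The fallen probes included a Rubisco subunit binding protein (pGT1_06891_01, -1.39 ± 0.16), which is a chaperonin, and a plastocyanin-like domain protein (pGT1_04833_01, -1.44 ± 0.13), a class that also occurs outside the chloroplast. The cell wall and expansion list was lower in leaf. In it 3 of 167 rose and 51 fell (list alone 3 and 54), among them an arabinogalactan protein (pGT1_05316_01, -4.81 ± 0.38) and expansin EXPA7 (pGT1_02521_01, -3.92 ± 0.40), a wall-loosening protein. The list had camera adjusted p = 0.000108, and adjusted p = 0.328 with an estimated correlation. Xylem and phloem markers were lower too, with 0 of 14 risen and 7 fallen, led by the fasciclin-like arabinogalactan proteins pGT1_03358_01, -4.84 ± 0.67 and pGT1_11737_02, -4.71 ± 0.69. Their camera adjusted p = 0.0108, and adjusted p = 0.328 with an estimated correlation, and with 1 probe per description the call was lost (adjusted p = 0.382).

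No other list shifted in camera between leaf and rhizome, although members moved both ways. Of the type III polyketide synthases, the enzyme family to which curcumin synthases belong, 2 of 23 rose and 4 fell. Every member carries a chalcone synthase description. They included chalcone synthase J (pGT1_02841_01, -2.61 ± 0.34), chalcone synthase 2 (pGT1_00213_01, -2.63 ± 0.54) and, higher in leaf, pGT1_00989_01, 1.29 ± 0.40. Of the phenylpropanoid and lignin enzymes, 7 of 52 rose and 6 fell, with 4-coumarate-CoA ligase lower (pGT1_04914_01, -1.96 ± 0.32) and cinnamoyl-CoA reductase higher (pGT1_08978_01, 2.07 ± 0.25). Of the terpene synthases, 0 of 12 rose and 2 fell: a sesquiterpene synthase (pGT1_03156_01, -3.43 ± 0.78, with -7.02 in FMO and 0.161 in TYA) and linalool synthase (pGT1_11455_01, -1.24 ± 0.30). Of the isoprenoid precursor pathways, 2 of 37 rose and 3 fell, including farnesyl pyrophosphate synthase (pGT1_00035_07, -3.00 ± 0.68) and geranylgeranyl reductase (pGT1_07882_01, 1.82 ± 0.21). Among cytochrome P450s 30 of 127 rose and 12 fell. Among genes of starch and sucrose metabolism 7 of 46 rose and 9 fell, with ADP-glucose pyrophosphorylase at pGT1_09320_01, 4.74 ± 0.20. Among lectins, chitinases and other defence proteins 10 of 83 rose and 13 fell, and chitinases moved both ways (pGT1_11744_01, 2.95 ± 0.16 and pGT1_00588_02, -2.92 ± 0.24). Among developmental transcription factors 8 of 64 rose and 8 fell, with NAC6 higher (pGT1_08205_01, 4.51 ± 0.23) and the homeobox protein GNARLY1 lower (pGT1_02112_01, -4.64 ± 0.36). In cell division 9 of 128 rose and 26 fell, and the 2 members with the smallest p among those that fell were tubulins (pGT1_00502_01, -1.96 ± 0.15 and pGT1_10340_01, -3.55 ± 0.33). Among auxin, cytokinin and gibberellin genes 16 of 123 rose and 16 fell. Among water and nutrient transporters 19 of 98 rose and 17 fell (list alone 20 and 20), with nitrate transporter NRT1-3 higher (pGT1_12295_01, 4.35 ± 0.33) and a tonoplast intrinsic protein, a water channel of the vacuole, lower (pGT1_00074_02, -4.17 ± 0.51). Among peroxidases and dirigent proteins 13 of 91 rose and 18 fell (list alone 14 and 18). Among ribosomal proteins 40 of 372 rose and 30 fell (list alone 36 and 23). Among heat shock and drought proteins 30 of 214 rose and 20 fell (list alone 27 and 19), with heat shock protein 90 at pGT1_00038_02, 4.10 ± 0.20. The list named organelle-encoded RNA matched mostly vacuolar ATP synthase subunits, proton pumps encoded in the nucleus, and 0 of 19 rose and 2 fell (list alone 0 and 1). The median, the mean and the camera direction did not all have the same sign for phenylpropanoid enzymes, terpene synthases, developmental transcription factors, hormone genes and ribosomal proteins.

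In all, limma called 3974 of 14160 probes between leaf and rhizome, 2156 higher and 1818 lower in leaf, 2839 of them by at least 2-fold. Of the calls, 1880 were also made in each variety by itself. On the 2 arrays that paired both sides within a variety, 36 of the 37 probes named here, all but pGT1_03156_01, and 91.2% of the calls so measured had the fit's direction on each. Within scan 3, 1261 probes were called and 99.8% of the calls had the same sign, while within scan 2, with 1 residual degree of freedom, limma called 0 (2281 at unadjusted p under 0.05) and 89% had the same sign. These arrays are part of the fit, so agreement on them or within a scan, here and below, is no independent check. Scan as a fixed block left 2727 calls.

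**Figure D1:**
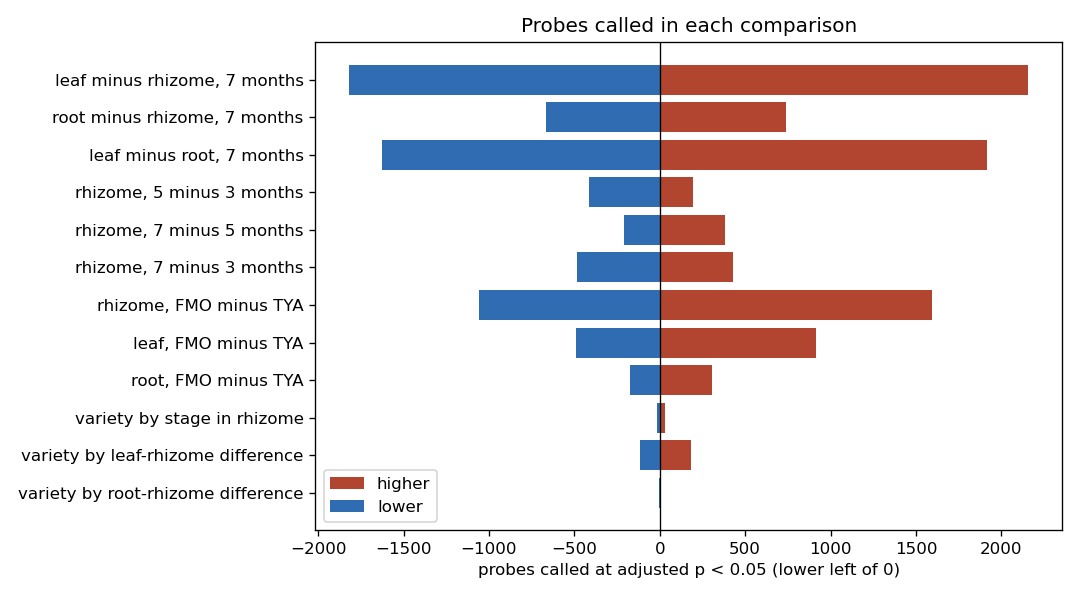
Number of probes called at adjusted p under 0.05 in each of the 12 comparisons, higher to the right and lower to the left of 0.

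The second comparison set root against rhizome at 7 months, with 7 root and 15 rhizome channels. Granule-bound starch synthase, which makes amylose, was lower in root by 2 probes (pGT1_07125_01, -3.91 ± 0.87 and pGT1_14235_01, -3.91 ± 0.90), as were chloroplast phosphoglucomutase (pGT1_00883_01, -3.98 ± 0.31) and plastidic glucan phosphorylase (pGT1_14881_01, -3.70 ± 0.49). The homeobox proteins OSH1 (pGT1_08756_01, -5.07 ± 0.58), KNAP3 (pGT1_00152_04, -4.69 ± 0.92) and GNARLY1 (pGT1_02112_01, -3.27 ± 0.34), of the knotted family that acts in shoot meristems, were lower in root too. Higher in root were NAR2.3, a partner protein of nitrate transporters (pGT1_11027_01, 5.14 ± 0.32), and a dTDP-glucose dehydratase (pGT1_10764_01, 5.29 ± 0.44). So were mitochondrial uncoupling protein 5 (pGT1_08165_01, 5.03 ± 0.45), a lipase-like protein (pGT1_12895_01, 4.17 ± 0.25), a cysteine protease (pGT1_14184_01, 4.08 ± 0.18) and a peroxidase (pGT1_08245_01, 3.86 ± 0.47).

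Cytochrome P450s, oxidases of secondary metabolism and hormone turnover, were the list that shifted upward in root: 14 of 127 rose and 3 fell, with pGT1_04696_01, 1.37 ± 0.19 and CYP72A5 (pGT1_04266_01, 2.33 ± 0.33) as examples. The list had camera adjusted p = 0.0452, and adjusted p = 0.684 with an estimated correlation, and scan as a fixed block (adjusted p = 0.0866) and 1 probe per description (0.761) ended the call. Of the polyketide synthases 3 of 23 rose and 0 fell (list alone 3 and 3), with chalcone synthase descriptions at pGT1_04948_01, 1.06 ± 0.23, pGT1_11833_01, 1.19 ± 0.27 and pGT1_00628_01, 1.19 ± 0.32. Among phenylpropanoid enzymes 2 of 52 rose and 1 fell, and a 4-coumarate-CoA ligase was at pGT1_00258_03, 2.24 ± 0.29. Of the terpene synthases 2 of 12 rose and 1 fell, with linalool synthase lower (pGT1_11455_01, -1.17 ± 0.28). Among starch and sucrose genes 1 of 46 rose and 5 fell, and alpha-amylase was at pGT1_00118_01, -1.44 ± 0.22. Among transporters 10 of 98 rose and 9 fell (list alone 10 and 10). They included the high-affinity nitrate transporter (pGT1_10716_01, 1.60 ± 0.18, with 0.132 in FMO and 3.07 in TYA) and aquaporin PIP1.3 (pGT1_00027_06, 2.08 ± 0.23), both higher in root, and a plasma membrane intrinsic protein that was lower (pGT1_06990_01, -2.65 ± 0.37). Among developmental transcription factors 7 of 64 rose and 7 fell (list alone 9 and 7), with NAC1 higher (pGT1_09608_01, 2.59 ± 0.29) and a knotted-like protein lower (pGT1_00009_08, -3.31 ± 0.40). Among cell wall genes 2 of 167 rose and 13 fell, with a xyloglucan endotransglycosylase higher (pGT1_07769_02, 3.18 ± 0.84) and expansin 1 lower (pGT1_01172_01, -1.81 ± 0.28). Among photosynthesis genes 8 of 161 rose and 4 fell, with the chlorophyll binding protein CP29.2 at pGT1_12391_01, 2.07 ± 0.15. The median, the mean and the camera direction did not all have the same sign for transporters and developmental transcription factors.

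limma called 1402 of 14196 probes between root and rhizome, 737 higher and 665 lower in root, 932 by at least 2-fold, and 206 were also called in each variety by itself. On the 1 array that paired both sides within a variety, 26 of the 27 probes measured there (29 named), all but pGT1_10716_01, and 96.5% of the calls so measured had the fit's direction. A scan held root of 1 variety at most: FMO in scan 2 (0 called, 3103 at unadjusted p under 0.05, 98% of the FMO calls with the same sign) and TYA in scan 3 (0 called, 2035 at unadjusted p under 0.05, 100%). Scan as a fixed block left 1229 calls, with median centring in place of loess 1160 (458 higher, 702 lower), from the arrays with leaf or root alone 552, and without the array of FMO rhizome with TYA root 788.

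Leaf was also set against root directly, with 8 and 7 channels. Among the highest in leaf were serine-glyoxylate aminotransferase (pGT1_05984_01, 7.96 ± 0.34), the photosystem II protein CP22 (pGT1_10745_01, 7.56 ± 0.36), fructose-bisphosphate aldolase (pGT1_09658_01, 7.56 ± 0.33) and phosphoribulokinase of the Calvin cycle (pGT1_05569_01, 7.04 ± 0.22). Higher in root were the type-2 metallothionein (pGT1_05035_01, -5.90 ± 0.37), vacuolar proton pyrophosphatase (pGT1_06268_01, -5.76 ± 0.43), sulfate transporter ATST1 (pGT1_00213_04, -5.65 ± 0.32), a germin-like protein (pGT1_04860_01, -5.12 ± 0.49) and the root-specific protein RCc3 (pGT1_05104_01, -5.02 ± 0.87). In the photosynthesis list 77 of 161 rose and 8 fell (list alone 85 and 11, camera adjusted p = 2.03e-16, and adjusted p = 0.128 with an estimated correlation). In the cell wall list 3 of 167 rose and 40 fell (camera adjusted p = 0.00162, and adjusted p = 0.507 with an estimated correlation). Among xylem and phloem markers 0 of 14 rose and 7 fell (list alone 0 and 8, camera adjusted p = 0.00162, and adjusted p = 0.29 with an estimated correlation), a call lost with 1 probe per description (adjusted p = 0.0932). The fallen photosynthesis probes included CP29.2 (pGT1_12391_01, -2.14 ± 0.14), which was also higher in root than in rhizome, and a plastocyanin-like domain protein (pGT1_00507_03, -3.00 ± 0.37). Of the polyketide synthases 0 of 23 rose and 5 fell, with the 2 C2-Idf-II chalcone synthase probes lower in leaf (pGT1_04948_01, -1.92 ± 0.20 and pGT1_11833_01, -1.90 ± 0.24). Among phenylpropanoid enzymes 5 of 52 rose and 8 fell, with hydroxycinnamoyl transferase higher (pGT1_03404_01, 2.13 ± 0.32) and 4-coumarate-CoA ligase lower in leaf (pGT1_00258_03, -2.88 ± 0.26). limma called 3542 of 14147 probes, 1918 higher and 1624 lower in leaf, 2274 by at least 2-fold, and 3073 with scan as a fixed block. On the 2 arrays that paired both sides within a variety, 13 of the 14 probes measured on both (15 named), all but pGT1_11833_01, and 86.7% of the calls so measured had the fit's direction on each. TYA leaf and root shared scan 3, where 505 probes were called and 100% of the TYA calls had the same sign. FMO leaf and root shared scan 2, where 0 were called (2196 at unadjusted p under 0.05) and 97.8% had the same sign.

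A probe was called rhizome-enriched when it was lower by at least 2-fold in both leaf and root, and 270 probes were, against 1038 for leaf and 207 for root by the same rule. Homeobox proteins of the knotted family were among the highest: OSH1 (pGT1_08756_01, 5.19 ± 0.68 over leaf and 5.07 ± 0.58 over root), KNAP3 (pGT1_00152_04, 5.95 ± 0.97 and 4.69 ± 0.92), GNARLY1 (pGT1_02112_01, 4.64 ± 0.36 and 3.27 ± 0.34) and TKN1 (pGT1_14779_01, 3.20 ± 0.51 and 2.83 ± 0.49). Others were taxane-type acyl transferase-like proteins (pGT1_00082_07, 6.51 ± 1.17 and 4.27 ± 1.11, and pGT1_09005_01, 4.65 ± 0.92 and 3.30 ± 0.87). Also enriched were an aspartic proteinase (pGT1_04512_01, 6.48 ± 0.73 and 4.23 ± 0.69) and agglutinin (pGT1_02245_01, 7.42 ± 0.94 and 3.05 ± 0.89). Granule-bound starch synthase was by pGT1_07125_01 (2.83 ± 0.92 and 3.91 ± 0.87). By pGT1_14235_01, FMO leaf (1.23) was no lower than 7-month FMO rhizome (0.896), though TYA leaf was (0.527 against 2.18). Of all probes 1.91% were rhizome-enriched. None of the 23 polyketide synthases was, which are too few to tell this apart from the share of all probes. For lectin and defence the share was 7.23% of 83 probes (6) and for cell wall 5.42% of 166 (9). Of 63 developmental transcription factors it was 7.94% (5). Fisher's exact test (2-sided, related probes taken as independent) gave all 3 adjusted p = 0.0419. Both comparisons shared rhizome channels, and lists of these sizes drawn independently would overlap by 30.9 probes. With leaf and root compared through different rhizome channels 144 probes were enriched, of which 131 were among the 270, and from the arrays with leaf or root alone 114 were.

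The stage comparisons asked how the rhizome changed as it grew, with 8 channels at 3 months, 8 at 5 months and 15 at 7 months. Among the probes that rose from 3 to 5 months were lectin GNA-1 (pGT1_00230_01, 6.13 ± 1.11), agglutinin (pGT1_02245_01, 5.49 ± 0.90), granule-bound starch synthase 1 (pGT1_14235_01, 4.54 ± 0.91), a patatin-like protein (pGT1_02273_01, 3.92 ± 0.81) and sucrose synthase (pGT1_00693_02, 3.79 ± 0.91). The phosphoenolpyruvate translocator (pGT1_12045_01, 4.40 ± 0.56) and cinnamate 4-hydroxylase, an early step of phenylpropanoid synthesis (pGT1_02760_02, 3.84 ± 0.87), rose as well. Small heat shock proteins fell, among them a class II protein (pGT1_00166_03, -4.56 ± 0.29) and a class 1 protein (pGT1_04349_01, -3.93 ± 0.64). So did nectarin III (pGT1_04588_01, -3.02 ± 0.36), a sulfate transporter (pGT1_07874_01, -2.83 ± 0.51), a type-2 metallothionein (pGT1_00093_04, -2.69 ± 0.42) and a photosystem II 10-kDa protein (pGT1_00516_03, -2.62 ± 0.59). The heat shock and drought list shifted down, with 2 of 214 risen and 25 fallen (list alone 4 and 34, camera adjusted p = 0.037, and adjusted p = 0.684 with an estimated correlation). So did photosynthesis, with 1 of 161 risen and 9 fallen (list alone 1 and 12, camera adjusted p = 0.0117, and adjusted p = 0.769 with an estimated correlation). The risen photosynthesis probe was Rubisco activase (pGT1_00040_04, 1.69 ± 0.24). The polyketide synthases shifted up although 1 of 23 rose and 0 fell. The called probe was a chalcone synthase (pGT1_00033_02, 1.39 ± 0.35), and the list had camera adjusted p = 0.0452, and adjusted p = 0.507 with an estimated correlation. The call was lost in 7 of 18 alternatives, among them 1 probe per description (adjusted p = 0.438), and kept with 15 of the 23 arrays left out in turn. Among starch and sucrose genes 4 of 46 rose and 1 fell. Among transporters 2 of 98 rose and 3 fell (list alone 3 and 3), and delta-tonoplast intrinsic proteins moved both ways (pGT1_11341_01, 3.40 ± 0.53 and pGT1_02472_01, -2.46 ± 0.49). Among cell wall genes 2 of 167 rose and 4 fell (list alone 1 and 4), with cellulose synthase 6 higher (pGT1_13066_01, 3.11 ± 0.74) and extensin, a wall protein, lower (pGT1_03817_01, -2.29 ± 0.34). Among developmental transcription factors 1 of 64 rose and 4 fell, with MADS-box protein PTM5 lower (pGT1_14247_01, -1.81 ± 0.25). The median, the mean and the camera direction did not all have the same sign for cell wall genes and developmental transcription factors.

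limma called 604 of 13805 probes from 3 to 5 months, 192 higher and 412 lower at 5 months, 409 by at least 2-fold. Tested by itself FMO had 18 calls and TYA 71, and limma called none of the 604 in both. On the 2 arrays that paired both sides within a variety, 8 of the 9 probes measured on both (20 named), all but pGT1_00693_02, and 74.7% of the calls so measured had the fit's direction on each, while pGT1_13066_01, measured on 1, had the other. Scan 1 held both stages of both varieties, called 0 (2015 at unadjusted p under 0.05), and 100% of the calls had the same sign in it. With scan as a fixed block 481 were called, 119 of them higher, and the camera call of heat shock and drought proteins was lost (adjusted p = 0.0563). Without the arrays that pair 3 and 5 months within a variety, one with the most outlier spots and one with ratios that correlated below 0 with those predicted, 932 probes were called, and from the rhizome-only arrays 213. With 1 array left out the count ranged from 72 (without TYA at 3 with FMO at 5 months) to 1080 (without TYA at 5 with TYA at 3 months).

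From 5 to 7 months the root-specific protein RCc3 (pGT1_05805_01, -5.52 ± 0.68), a P450-like protein (pGT1_12542_01, -4.14 ± 0.76), a BURP domain protein (pGT1_05782_01, -3.92 ± 0.46), the phosphoenolpyruvate translocator (pGT1_12045_01, -3.21 ± 0.56) and sulfate transporter ATST1 (pGT1_00213_04, -3.10 ± 0.40) were among the lowest at 7 months. Among the highest were a type 3 metallothionein (pGT1_00313_01, 3.65 ± 0.58), KNAP3 (pGT1_00152_04, 3.30 ± 0.80), and a purple acid phosphatase (pGT1_00553_03, 3.15 ± 0.59). Also higher were the MYB17 transcription factor (pGT1_00002_014, 2.89 ± 0.27), a cysteine protease (pGT1_02177_01, 2.47 ± 0.25), the clock-associated response regulator PRR95 (pGT1_13807_01, 2.19 ± 0.31) and phytoene synthase, an enzyme of carotenoid synthesis (pGT1_10066_01, 2.10 ± 0.47). Genes of the cell wall shifted down, with 3 of 167 risen and 17 fallen (list alone 4 and 29, camera adjusted p = 3.88e-08, and adjusted p = 0.183 with an estimated correlation). They included a polygalacturonase (pGT1_14180_01, -3.10 ± 0.39) and xyloglucan endotransglycosylase XET2 (pGT1_08902_01, -2.41 ± 0.32), while expansin 1 rose (pGT1_01172_01, 1.32 ± 0.25). Cell division shifted down, with 0 of 128 risen and 7 fallen (list alone 2 and 15, camera adjusted p = 0.000233, and adjusted p = 0.253 with an estimated correlation), and tubulins were among the fallen (pGT1_01702_01, -1.04 ± 0.19 and pGT1_00502_01, -0.58 ± 0.12). Peroxidases and dirigent proteins shifted down, with 1 of 91 risen and 4 fallen (list alone 3 and 5, camera adjusted p = 0.037, and adjusted p = 0.507 with an estimated correlation), led by pGT1_00027_11, -1.64 ± 0.23 and pGT1_00221_01, -2.33 ± 0.40. Xylem and phloem markers shifted down although 0 of 14 rose and 0 fell (camera adjusted p = 0.00315, and adjusted p = 0.298 with an estimated correlation), a call lost with 1 probe per description (adjusted p = 0.434). Among starch and sucrose genes 4 of 46 rose and 0 fell (list alone 9 and 0), with alpha-amylase (pGT1_00118_01, 1.38 ± 0.19) and sucrose phosphate synthase (pGT1_06606_01, 1.13 ± 0.18) as examples. Among isoprenoid precursor pathways 2 of 37 rose and 0 fell, with geranylgeranyl diphosphate synthase at pGT1_07816_01, 1.47 ± 0.39. Of the terpene synthases 0 of 12 rose and 1 fell (pGT1_03268_02, -1.16 ± 0.26). None of the 23 polyketide synthases was called (list alone 3 risen and 0 fallen).

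limma called 591 of 13977 probes from 5 to 7 months, 381 higher and 210 lower, 341 by at least 2-fold. Tested by itself FMO had 386 calls and TYA 20, a difference that was not tested. On the 2 arrays that paired both sides within a variety, 18 of the 19 probes measured on both (23 named), all but pGT1_01702_01, and 76.5% of the calls so measured had the fit's direction on each, while pGT1_00313_01, measured on 1, had the other. RCc3 and pGT1_12045_01 were measured on neither. Within scan 1, 0 were called (796 at unadjusted p under 0.05) and 89.9% of the calls had the same sign. With scan as a fixed block 230 were called (121 higher, 109 lower), and the camera call of peroxidases and dirigent proteins was lost (adjusted p = 0.144, and 0.382 with 1 probe per description). With median centring in place of loess 645 were (98 higher, 547 lower), and without a dye term 301 (157 higher, 144 lower). With 1 array left out the count ranged from 103 (without FMO at 5 with TYA at 7 months) to 1279 (without FMO at 5 with FMO at 7 months).

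Over the whole span, from 3 to 7 months, lectin GNA-1 (pGT1_00230_01, 7.75 ± 1.01) and agglutinin (pGT1_02245_01, 7.29 ± 0.95) were among those that rose the furthest, with the 7-month spots saturated as above. Also far up were KNAP3 (pGT1_00152_04, 5.30 ± 0.92), a delta-tonoplast intrinsic protein (pGT1_11341_01, 5.11 ± 0.54), granule-bound starch synthase (pGT1_07125_01, 3.93 ± 0.87 and pGT1_14235_01, 3.83 ± 0.96) and phosphoglucomutase (pGT1_00883_01, 3.57 ± 0.44). Sulfate transporter ATST1 (pGT1_00213_04, -5.11 ± 0.55), a class II small heat shock protein (pGT1_00166_03, -5.03 ± 0.26), type-2 metallothioneins (pGT1_05035_01, -4.95 ± 0.42 and pGT1_00093_04, -4.24 ± 0.48), a BURP domain protein (pGT1_10705_01, -4.20 ± 0.72), a glycine-rich protein (pGT1_01027_01, -4.07 ± 0.84) and a class 1 small heat shock protein (pGT1_06224_01, -3.93 ± 0.58) were among those that fell the furthest. The class II protein was at -2.94 in FMO and -7.11 in TYA. One chalcone synthase rose (pGT1_00033_02, 2.49 ± 0.40), as did 2 probes of phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway (pGT1_03925_01, 1.35 ± 0.29 and pGT1_12209_01, 1.81 ± 0.41), and geranylgeranyl diphosphate synthase (pGT1_03289_01, 2.63 ± 0.48). In the list of polyketide synthases 1 of 23 rose and 0 fell (camera adjusted p = 0.0452, and adjusted p = 0.507 with an estimated correlation), a call lost with 1 probe per description (adjusted p = 0.434). Among phenylpropanoid enzymes 3 of 52 rose and 1 fell, and cinnamoyl-CoA reductase was the one that fell (pGT1_08978_01, -1.64 ± 0.25).

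Among starch and sucrose genes 6 of 46 rose and 0 fell (list alone 10 and 0), which did not pass camera (adjusted p = 0.0748). Cell wall genes shifted down, with 2 of 167 risen and 20 fallen (list alone 3 and 27, camera adjusted p = 0.000206, and adjusted p = 0.328 with an estimated correlation), among them a xyloglucan endotransglycosylase (pGT1_00061_04, -3.75 ± 0.58) and extensin (pGT1_03817_01, -2.66 ± 0.39). Cell division shifted down, with 1 of 128 risen and 6 fallen (camera adjusted p = 0.00162, and adjusted p = 0.298 with an estimated correlation). Cyclin D fell (pGT1_00684_02, -1.06 ± 0.25), and a histone H3 rose (pGT1_00006_50, 1.82 ± 0.28). Heat shock and drought proteins shifted down, with 8 of 214 risen and 27 fallen (list alone 10 and 30, camera adjusted p = 0.0111, and adjusted p = 0.597 with an estimated correlation), and metallothioneins, which bind metals, were among the fallen. Photosynthesis shifted down, with 2 of 161 risen and 9 fallen (list alone 2 and 12, camera adjusted p = 0.0452, and adjusted p = 0.876 with an estimated correlation), photosystem I subunit XI falling (pGT1_07139_01, -1.62 ± 0.29) and plastocyanin rising (pGT1_13410_01, 1.26 ± 0.18). Xylem and phloem markers shifted down, with 0 of 14 risen and 1 fallen (list alone 0 and 3, camera adjusted p = 0.0452, and adjusted p = 0.507 with an estimated correlation), the called probe being a fasciclin-like protein (pGT1_06533_01, -1.48 ± 0.33). NAC domain factors rose (pGT1_08205_01, 1.36 ± 0.22 and pGT1_07107_01, 2.43 ± 0.39) and MADS-box protein PTM5 fell (pGT1_14247_01, -1.95 ± 0.29), where 4 of 64 rose and 4 fell (list alone 5 and 5).

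limma called 909 of 13820 probes from 3 to 7 months, 426 higher and 483 lower at 7 months, 654 by at least 2-fold, and 176 were also called in each variety by itself. On the 2 arrays that paired both sides within a variety, 25 of the 25 probes measured on both (29 named) and 95.6% of the calls so measured had the fit's direction on each. Within scan 1, 0 were called (714 at unadjusted p under 0.05) and 90% of the calls had the same sign. With scan as a fixed block 514 were called (186 higher, 328 lower) and the camera calls of photosynthesis, cell division, heat shock and drought proteins and xylem and phloem markers were lost (adjusted p = 0.34, 0.096, 0.0871 and 0.163), as were those of photosynthesis and of xylem and phloem markers with 1 probe per description (0.0932 and 0.757). With median centring in place of loess 989 were called (169 higher, 820 lower), and without the array of TYA at 7 and 3 months 381.

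**Figure D2:**
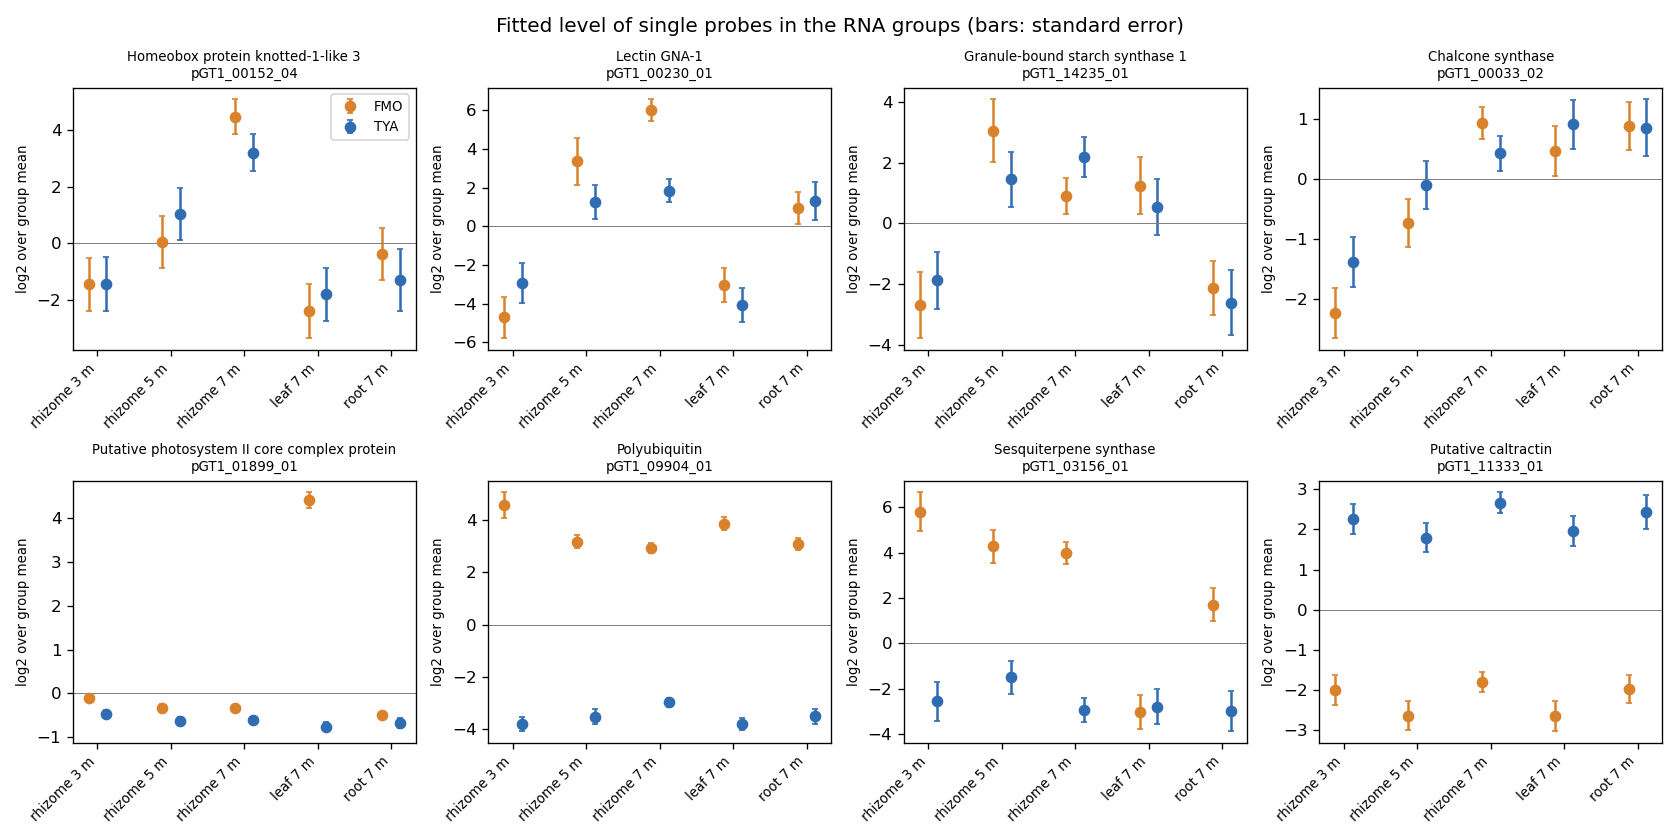
Fitted level of 8 probes in the 10 RNA groups, as log2 over the mean of the groups, with the standard error of the fit as bars; FMO is drawn in orange and TYA in blue. Lectin GNA-1 and granule-bound starch synthase 1 lay lowest in the 3-month rhizome among rhizome groups, and polyubiquitin lay higher in FMO than in TYA in every organ and stage.

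The varieties were compared within each organ. In the rhizome, over its 3 stages and with 16 FMO and 15 TYA channels, a proline-rich protein (pGT1_00076_07, 7.28 ± 0.41), a sesquiterpene synthase, which makes volatile terpenes (pGT1_03156_01, 7.02 ± 0.62), a polyubiquitin probe (pGT1_09904_01, 7.01 ± 0.22), sucrose synthase (pGT1_06131_02, 7.01 ± 1.45) and glutaredoxin (pGT1_12727_02, 7.00 ± 0.56) were among the highest in FMO. A fasciclin-like protein (pGT1_00992_01, 5.82 ± 0.44) and a taxadienol acetyl transferase-like protein (pGT1_03760_01, 5.79 ± 0.53) were also higher. Higher in TYA were an aminopeptidase N (pGT1_11479_01, -5.12 ± 0.30), caltractin, a calcium-binding protein (pGT1_11333_01, -4.40 ± 0.27), an aldehyde dehydrogenase (pGT1_12064_01, -4.05 ± 0.50), fructose bisphosphate aldolase (pGT1_00007_07, -3.56 ± 0.28), a small heat shock protein (pGT1_00565_01, -3.53 ± 0.44) and a cytochrome P450 (pGT1_00643_01, -3.27 ± 0.50). Of the polyketide synthases 2 of 23 rose and 0 fell, which were 2 chalcone synthases (pGT1_00628_01, 1.28 ± 0.23, the same on 1 of 3 paired arrays, and pGT1_00213_01, 2.31 ± 0.46). Among phenylpropanoid enzymes 7 of 52 rose and 4 fell (list alone 8 and 4). Cinnamate 4-hydroxylase (pGT1_00037_02, 2.86 ± 0.48) and hydroxycinnamoyl transferase (pGT1_03404_01, 1.87 ± 0.27) were higher in FMO, and the 2 lower probes named by the rule were prolyl 4-hydroxylases (pGT1_08881_01, -0.39 ± 0.08 and pGT1_05834_01, -0.76 ± 0.16). Of the terpene synthases 3 of 12 rose and 1 fell (list alone 4 and 1), with linalool synthase higher (pGT1_11455_01, 1.72 ± 0.21). Sesquiterpene synthase 1 was the lower one (pGT1_13793_01), at least 1.31-fold, since its probe was not above background in any FMO channel. Among isoprenoid precursor genes 4 of 37 rose and 3 fell (list alone 5 and 3), with 1-deoxy-D-xylulose-5-phosphate synthase higher (pGT1_09664_01, 2.28 ± 0.39) and geranylgeranyl diphosphate synthase lower (pGT1_03289_01, -1.97 ± 0.36).

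No list shifted between the varieties in the rhizome in camera. Among ribosomal proteins 32 of 372 rose and 48 fell (list alone 34 and 50), for example L19 (pGT1_06443_01, 3.18 ± 0.15) and L7A (pGT1_11504_01, -3.03 ± 0.16). Among heat shock and drought proteins 42 of 214 rose and 10 fell (list alone 45 and 10), with a class 1 small heat shock protein at pGT1_00383_01, 3.32 ± 0.22. Among cytochrome P450s 17 of 127 rose and 12 fell, with pGT1_00435_02, 4.58 ± 0.48 and pGT1_00030_08, -2.86 ± 0.17. Among photosynthesis genes 21 of 161 rose and 5 fell (list alone 20 and 5). Among lectins and defence proteins 8 of 83 rose and 6 fell, with beta-1,3-glucanases, which degrade fungal walls, higher in FMO (pGT1_02576_01, 2.79 ± 0.15 and pGT1_14706_01, 2.06 ± 0.18). Among cell wall genes 16 of 167 rose and 8 fell (list alone 15 and 7), with pectin methylesterase higher (pGT1_00986_01, 3.82 ± 0.35) and an extensin-like protein lower (pGT1_04931_01, -2.70 ± 0.51). Among transporters 6 of 98 rose and 5 fell, with a tonoplast intrinsic protein at pGT1_06795_01, 3.92 ± 0.30. Among peroxidases and dirigent proteins 9 of 91 rose and 5 fell (list alone 8 and 5), with glutathione peroxidase higher (pGT1_02745_01, 4.22 ± 0.38) and ascorbate peroxidase lower (pGT1_12425_01, -2.73 ± 0.24). Among hormone genes 8 of 123 rose and 5 fell (list alone 5 and 2), with auxin response factor 10 at pGT1_00198_03, 4.36 ± 0.36. Among cell division genes 15 of 128 rose and 5 fell. Among developmental transcription factors 7 of 64 rose and 5 fell. In starch and sucrose metabolism 5 of 46 rose and 6 fell. The median, the mean and the camera direction did not all have the same sign for phenylpropanoid enzymes, terpene synthases, isoprenoid precursor pathways, cell wall genes, transporters, hormone genes, cell division, developmental transcription factors and starch and sucrose metabolism.

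limma called 2650 of 13798 probes between the varieties in the rhizome, 1592 higher and 1058 lower in FMO, 1389 by at least 2-fold. By stage, 1084 were called at 3 months, 858 at 5 months and 2171 at 7 months. On the 3 arrays that paired a rhizome of FMO with one of TYA of the same age, 25 of the 27 probes measured on all (35 named), all but pGT1_00628_01 and pGT1_05834_01, and 68.8% of the calls so measured had the fit's direction on each. Within scan 1, 0 were called (1882 at unadjusted p under 0.05) and 98.9% of the calls had the same sign, and with scan as a fixed block 2332 were called.

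In leaf, with 4 FMO and 4 TYA channels, glutaredoxin (pGT1_12727_02, 8.39 ± 0.87), polyubiquitin (pGT1_09904_01, 7.69 ± 0.28), catalase 2 (pGT1_00667_01, 7.34 ± 0.69), a chloroplast thioredoxin M (pGT1_01137_02, 6.49 ± 0.37) and glutamine synthetase (pGT1_00265_05, 6.23 ± 0.77) were among the highest in FMO. Caltractin (pGT1_11333_01, -4.61 ± 0.46), aminopeptidase N (pGT1_11479_01, -4.53 ± 0.52), a glycine-rich RNA-binding protein (pGT1_00034_08, -4.46 ± 0.44), Knotted 3 (pGT1_02159_01, -4.00 ± 0.26) and ferredoxin I, an electron carrier of photosynthesis (pGT1_05238_01, -3.97 ± 0.28), were among the lowest. Photosynthesis shifted toward FMO, with 20 of 161 risen and 4 fallen (list alone 22 and 6, camera adjusted p = 0.0452, and adjusted p = 0.876 with an estimated correlation). They include a psbY protein (pGT1_01899_01, 5.18 ± 0.21), no higher in TYA leaf than in TYA rhizome. Others are plastocyanin (pGT1_13410_01, 2.59 ± 0.24) and, higher in TYA, a light-harvesting protein (pGT1_00008_24, -1.93 ± 0.40). Starch branching enzyme I (pGT1_03995_01, 4.23 ± 0.26) and hydroxycinnamoyl transferase (pGT1_03404_01, 3.93 ± 0.46) were higher in FMO. In starch and sucrose metabolism 1 of 46 rose and 3 fell, and among phenylpropanoid enzymes 3 of 52 rose and 2 fell. One chalcone synthase was higher in TYA (pGT1_03064_01, -1.18 ± 0.30), with 0 of 23 risen and 1 fallen. The median, the mean and the camera direction did not all have the same sign for these 3 lists. limma called 1404 of 14190 probes, 916 higher and 488 lower in FMO, 1144 by at least 2-fold, and 1402 with scan as a fixed block. On the 1 array that paired both leaves, 14 of the 14 probes measured there (16 named) and 99.8% of the calls so measured had the fit's direction. Within scan 3, 76 were called and 99.9% of the calls had the same sign, and within scan 2, 0 were called (3161 at unadjusted p under 0.05) and 97.3% had the same sign. With median centring 1208 were called (964 higher, 244 lower). From the arrays with leaf or root alone 772 were, and with scan as a fixed block the photosynthesis call was lost (adjusted p = 0.0595, and 0.109 with 1 probe per description).

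In root, with 4 FMO and 3 TYA channels, polyubiquitin (pGT1_09904_01, 6.63 ± 0.34), a B12D protein (pGT1_09036_01, 5.71 ± 0.70), glutamine synthetase (pGT1_00265_05, 5.56 ± 0.72) and the sesquiterpene synthase (pGT1_03156_01, 4.69 ± 1.15) were among the highest in FMO. A xylose isomerase (pGT1_00305_02) was at least 32.4-fold higher, since it was above background in 0 of the 3 TYA channels. Caltractin (pGT1_11333_01, -4.43 ± 0.56), actin-depolymerizing factor 1 (pGT1_07423_01, -4.15 ± 0.59), a Rubisco probe (pGT1_11040_01, -3.95 ± 0.56) and aminopeptidase N (pGT1_11479_01, -3.94 ± 0.63) were among the lowest. The photosynthesis list shifted toward FMO, with 6 of 161 risen and 0 fallen (list alone 8 and 1, camera adjusted p = 0.00817, and adjusted p = 0.769 with an estimated correlation), among them CP29.2 (pGT1_12391_01, 1.39 ± 0.24), whose value turned to -0.0446 with scanner-processed signals. The high-affinity nitrate transporter was higher in TYA (pGT1_10716_01, -2.82 ± 0.29), where 0 of 98 rose and 3 fell among transporters. No polyketide synthase was called. limma called 480 of 14182 probes, 305 higher and 175 lower in FMO, 436 by at least 2-fold, and 447 with scan as a fixed block. All FMO root arrays were in scan 2 and all TYA root arrays in scan 3, and no array paired both roots, so no within-scan value exists. With median centring 394 were called (331 higher, 63 lower), from the arrays with leaf or root alone 42, and without the array of FMO rhizome with TYA root 201.

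Interaction terms tested whether the varieties differed in their change. For the rhizome change from 3 to 7 months 46 of 13842 probes were called, 28 higher and 18 lower in FMO than in TYA. Heat shock proteins led the higher ones: class 1 and class II small heat shock proteins (pGT1_05224_01, 6.97 ± 0.97, pGT1_00663_02, 5.85 ± 1.01, pGT1_00565_01, 5.45 ± 0.87 and pGT1_00166_03, 4.16 ± 0.38) and dnaJ 8 (pGT1_01420_01, 4.64 ± 0.51), an accessory chaperone. For all 5 the change from 3 to 7 months was negative in TYA and higher in FMO (for example -6.76 against 0.204 for pGT1_05224_01). Ribosomal protein L19 (pGT1_04176_01, 2.68 ± 0.28) and S-adenosylmethionine synthetase (pGT1_08132_02, 3.09 ± 0.50) were also higher, and a terpenoid synthase (pGT1_10261_01, -4.20 ± 0.76) and a proline-rich protein (pGT1_11410_01, -4.09 ± 0.67) were lower. The terpene synthases shifted down, although 0 of 12 rose and 0 fell (camera adjusted p = 0.0218, and adjusted p = 0.522 with an estimated correlation). The heat shock list did not shift, with 6 of 214 risen and 0 fallen (list alone 12 and 3). Scan as a fixed block left 6 calls, with median centring 37 (27 higher, 10 lower), and from the rhizome-only arrays limma called 0 (1248 at unadjusted p under 0.05).

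For the difference between leaf and rhizome 296 of 14163 probes were called, 182 higher and 114 lower in FMO. Among the highest were a cytochrome P450 (pGT1_02222_01, 5.91 ± 0.77), a metallo-beta-lactamase-like protein (pGT1_14862_01, 5.29 ± 0.40), the photosystem proteins psaK (pGT1_12081_02, 5.15 ± 0.54) and psbY (pGT1_01899_01, 4.91 ± 0.22) and thioredoxin M (pGT1_01137_02, 4.69 ± 0.43). Among the lowest were a taxadienol acetyl transferase-like protein (pGT1_03760_01, -7.51 ± 1.05), the sesquiterpene synthase (pGT1_03156_01, -7.18 ± 1.09), benzoyl transferase (pGT1_05010_01, -6.21 ± 0.75), a dioxygenase (pGT1_09683_01, -5.37 ± 1.12), a proline-rich protein (pGT1_00076_07, -5.29 ± 0.82) and C-4 sterol methyl oxidase (pGT1_02278_01, -5.05 ± 0.29). Both C2-Idf-II chalcone synthase probes were higher (pGT1_04948_01, 1.53 ± 0.34 and pGT1_11833_01, 1.73 ± 0.40), where 2 of 23 rose and 0 fell (list alone 2 and 1). Xylem and phloem markers shifted down, with 0 of 14 risen and 1 fallen (camera adjusted p = 0.037, and adjusted p = 0.507 with an estimated correlation), and the call was lost with scan as a fixed block (adjusted p = 0.0599) and with 1 probe per description (0.374). Scan as a fixed block left 278 calls. With median centring 235 were called (178 higher, 57 lower), from scanner-processed signals 97 (40 higher, 57 lower) and from the deposited table of log ratios 103 (40 higher, 63 lower). From the arrays with leaf or root alone limma called 0 (1089 at unadjusted p under 0.05).

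For the difference between root and rhizome 4 of 14182 probes were called: C-4 sterol methyl oxidase (pGT1_02278_01, -4.43 ± 0.35), the high-affinity nitrate transporter (pGT1_10716_01, -2.94 ± 0.35), an NBS-LRR disease resistance protein (pGT1_00082_02, -2.62 ± 0.37) and, named after its value was seen, a probe without product description (pGT1_12930_01_as, 3.17 ± 0.43). At unadjusted p under 0.05, 1166 probes passed, and from the arrays with leaf or root alone limma called 0 (1030 at unadjusted p under 0.05). Without the array of FMO rhizome with TYA root 92 were called.

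**Figure D3:**
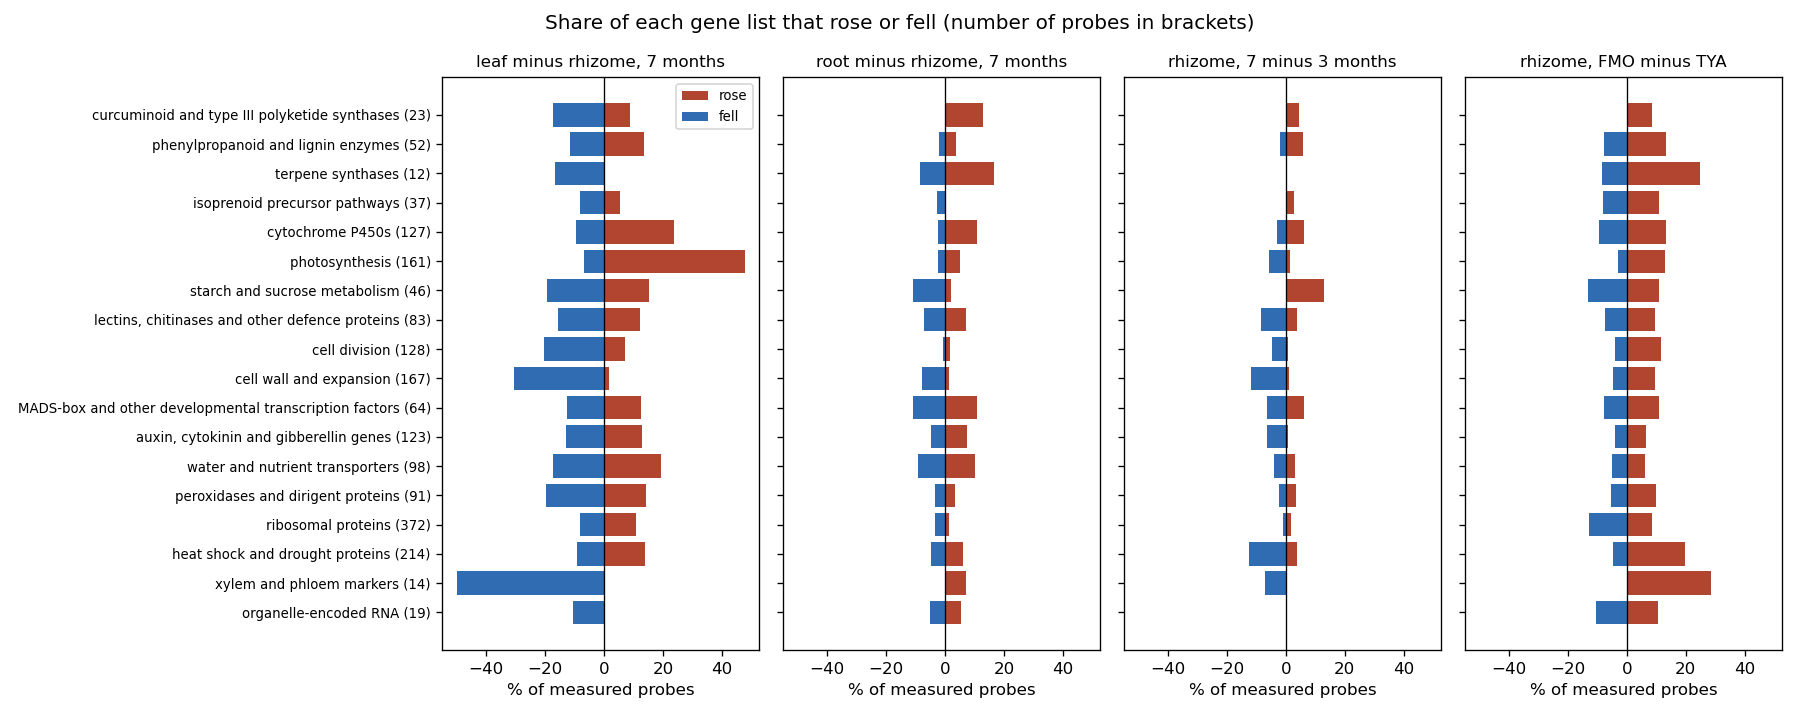
Percentage of the measured probes of each of the 18 gene lists that rose (right of 0) or fell (left of 0) at adjusted p under 0.05 in 4 comparisons.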

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

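The tests of an effect of arrays or scans, of probes with the same description and of moved residuals, and both tests of the array labelled TYA root in both channels, were chosen after the results were seen; the others were set beforehand. Differences between the varieties in a change were tested as interaction terms, and these were called. In the rhizome change from 3 to 7 months 46 probes differed. Named ones were class 1 and class II small heat shock proteins (pGT1_05224_01 6.97, pGT1_00663_02 5.85, pGT1_00565_01 5.45 and pGT1_00166_03 4.16), dnaJ 8 (pGT1_01420_01 4.64), S-adenosylmethionine synthetase (pGT1_08132_02 3.09), ribosomal protein L19 (pGT1_04176_01 2.68), a terpenoid synthase (pGT1_10261_01 -4.20) and a proline-rich protein (pGT1_11410_01 -4.09), as log2 FMO minus TYA. In leaf minus rhizome 296 probes differed. Those named above were pGT1_02222_01 (5.91), pGT1_14862_01 (5.29), psaK (pGT1_12081_02 5.15), psbY (pGT1_01899_01 4.91), thioredoxin M (pGT1_01137_02 4.69), chalcone synthases C2-Idf-II (pGT1_11833_01 1.73 and pGT1_04948_01 1.53), a chitinase (pGT1_11744_01 -1.39), C-4 sterol methyl oxidase (pGT1_02278_01 -5.05), pGT1_00076_07 (-5.29), pGT1_09683_01 (-5.37), pGT1_05010_01 (-6.21), the sesquiterpene synthase (pGT1_03156_01 -7.18) and pGT1_03760_01 (-7.51). In root minus rhizome 4 did: pGT1_02278_01 (-4.43), the high-affinity nitrate transporter (pGT1_10716_01 -2.94), an NBS-LRR protein (pGT1_00082_02 -2.62) and pGT1_12930_01_as (3.17). On the array labelled TYA root in both channels, not used in the comparisons, 18.3% of probes were beyond 2-fold.

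Other assignments of the 23 arrays to the labelled pairs, 100 for each count with the real one included, tested whether chance gives as many calls. For leaf minus rhizome 1 of 100, the real one, gave as many (3974, highest other 262), and likewise 1 for root minus rhizome (1402, 5), leaf minus root (3542, 1075), 5 minus 3 months (604, 2), 7 minus 5 months (591, 7), 7 minus 3 months (909, 2), rhizome FMO minus TYA (2650, 92), leaf FMO minus TYA (1404, 197), root FMO minus TYA (480, 5), variety by leaf (296, 17) and rhizome-enriched probes (270, 0, from limma calls). For variety by stage 2 of 100 gave as many (46, highest other 163), and for variety by root 2 of 100 (4, highest other 10). The 163 calls, several times the real 46, point to a structure of the arrays, which was not tested further. These assignments mix organs and so enlarge the spread, which leaves few calls whatever the real count. A second test kept all other differences and moved the residuals between arrays. As many calls came from 1 of 100 in 9 of the comparisons, from 2 for 7 minus 5 months (highest other 1049) and variety by leaf (298), and from 3 for variety by root (195, also several times the real 4). For variety by stage it was 1, with 3 as the highest other. Chance between plants, which the labels do not tell apart, was untested. In grouping arrays, chance is argued against for the 8 comparisons where no other assignment reached the real count in either test. For 7 minus 5 months and the 3 interactions it stays open, although the shares are under 0.05. Of the 99 moves, 92 to 96 gave 0 calls in each comparison, so the shares say little about how large a count is.

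Many probes differed between FMO and TYA by similar amounts in every organ: r across probes was 0.655 for rhizome and leaf, 0.552 for rhizome and root and 0.566 for leaf and root, where data simulated without differences gave 0.079, -0.049 and -0.031. In 7-month rhizome an effect of single arrays or scans is argued against by scans 1 and 3, which share no array (r 0.545). In root scan and variety coincide, and leaf was untested. Sequence differences under the probes may contribute. Of pairs of probes with the same description, both called, 27.4% of 234 had opposite signs for rhizome FMO minus TYA. For leaf minus rhizome it was 16.9% of 644, 10.4 percentage points fewer (Fisher's exact test, 2-sided, p = 0.00104). Pairs share probes, which this p ignores. Probes sharing a number (-0.997 points) decide nothing, since 3.06% of their pairs share a description. Differences in transcript level, the biological explanation that the design names, stay open and were not separated from sequence.

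Of the heat shock and drought list, 6 members differed between the varieties in their change from 3 to 7 months, with a median of 5.65 (log2), and all 6 had a lower value at 3 months in FMO than in TYA (-6.87 to -1.51). In 5 of them FMO was higher at 5 months (0.515 to 5.2) and at 7 months (2.54 to 4.69), while pGT1_00565_01 was lower at both (-2.31 and -1.42). The 6 were picked by this difference, so their median cannot exclude 1 array or scans as the source. It was at least 4.51 with any array left out and 4.83 with scan as a fixed block. There 1 of the 6 was still called, and 6 probes in place of 46 in the comparison, with a median standard error of 1.02 in place of 0.921 and 11 residual degrees of freedom in place of 13. What ended the calls was not tested. Conditions at the harvest of the 3-month TYA plants cannot be told apart from variety: the list's heat shock protein 70, 90, 100 and dnaJ probes, 85 in number, had a median of -0.0639 (quartiles -0.365 and 0.244), which goes both ways, and harvest and group coincide in the labels. A difference in development between the varieties stays open, untested.

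The array labelled TYA root in both channels had log2 ratios with a standard deviation of 0.871. Dye bias or noise as the whole source is argued against by an r across probes of 0.536 with TYA rhizome at 5 months minus TYA root, the dye term taken off, the highest of 45 differences between groups. RNA of another group in 1 channel is a candidate: the 3 highest values all involved TYA root (0.536, 0.491 and 0.409 for TYA rhizome at 5, 3 and 7 months). The highest that did not was 0.407, a small gap, so which group it may be stays open. The array was not relabelled, and no biological explanation was tested.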

How the results depend on the processing

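The alternatives that leave out 2 arrays, the probes named _as and all but 1 probe per description, and the comparison through different rhizome channels, were chosen after the data were examined. Of the 240 values of single probes named in the report, none changed direction in any alternative or with 1 array left out, except 1: CP29.2 (pGT1_12391_01) in root, FMO minus TYA, was 1.39 in the report and -0.0446 both from scanner-processed signals and from the deposited log ratios; the cause was not tested. Over all settings 9248 of 9806 such values kept their call, 556 lost it and 2 changed sign, and 132 of the 240 kept it throughout: 34 of 37 in leaf minus rhizome, 15 of 15 in leaf minus root, 26 of 35 in rhizome FMO minus TYA, 18 of 29 in root minus rhizome, 17 of 29 in 7 minus 3 months, 9 of 16 in leaf FMO minus TYA, 8 of 23 in 7 minus 5 months, 5 of 20 in 5 minus 3 months, and 0 in root FMO minus TYA and in the interactions, as counted over the same limma models.

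The counts of leaf minus rhizome (2727 to 4116) and leaf minus root (2572 to 3810) stayed within 1.5 times those of the report in 18 of 18 alternatives and with each of the 23 arrays left out. Rhizome FMO minus TYA (1428 to 3176) did in 17 of 18, root minus rhizome in 16, leaf FMO minus TYA in 16, variety by root in 14, 7 minus 5 and 7 minus 3 months in 14 each, 5 minus 3 months and root FMO minus TYA in 13, variety by leaf in 12 and variety by stage in 7 of 18. From scanner-processed signals the counts were root FMO minus TYA 276, variety by stage 19, variety by leaf 97 and rhizome-enriched 409. With median centring the count was 5 minus 3 months 325. With the strict filter, which tests fewer probes, the counts were variety by stage 23, variety by leaf 182 and variety by root 2. Without a dye term the counts were 5 minus 3 months 315, 7 minus 5 months 301, 7 minus 3 months 533, root FMO minus TYA 246 and variety by stage 20. With scan as a fixed block the counts were 7 minus 5 months 230, 7 minus 3 months 514 and variety by stage 6. From the rhizome-only arrays, fewer than in the full model, the counts were 5 minus 3 months 213 and variety by stage 0 (1248 at unadjusted p under 0.05 in limma). From the arrays with leaf or root alone, also fewer, the counts were root minus rhizome 552, leaf FMO minus TYA 772, root FMO minus TYA 42, variety by leaf 0 (1089 at unadjusted p under 0.05 in limma), variety by root 0 (1030 at unadjusted p under 0.05 in limma) and rhizome-enriched 114. With the ratio of the array of TYA (Cy3) and FMO (Cy5) rhizome at 7 months turned the counts were root minus rhizome 927, 5 minus 3 months 281, 7 minus 5 months 249, 7 minus 3 months 553, rhizome FMO minus TYA 1428, leaf FMO minus TYA 537, root FMO minus TYA 12, variety by stage 9, variety by leaf 124, variety by root 2 and rhizome-enriched 175. With that array left out the count was variety by stage 25. With trend and robust eBayes the count was variety by stage 30. With arrayWeights (0.266 to 2.21) the counts were 7 minus 5 months 2021, 7 minus 3 months 1419, variety by stage 166 and variety by leaf 464. From the deposited log ratios the counts were root FMO minus TYA 286, variety by stage 20, variety by leaf 103, variety by root 2 and rhizome-enriched 412. Without the 2 doubted arrays the counts were 5 minus 3 months 932 and variety by stage 21. With leaf and root compared through different rhizome channels the count was rhizome-enriched 144. Without a filter the count was list shifts 15. With the estimated correlation in camera the count was list shifts 0 (18 at unadjusted p under 0.05 in camera). Apart from the settings with fewer probes or arrays, the cause was not tested. The median of all probes was -0.0168 in leaf minus rhizome and -0.0289 in rhizome FMO minus TYA in the report, -0.124 and -0.105 from scanner-processed signals, and -0.134 and -0.116 from the deposited log ratios. Of the list shifts, photosynthesis and cell wall in both leaf comparisons, photosynthesis in 5 minus 3 months, and cell division and cell wall in 7 minus 5 months kept their camera call in 18 of 18 alternatives of the values, as did cell wall in 7 minus 3 months; with 1 array left out photosynthesis in 5 minus 3 months kept it in 21 of 23 and the others in all. Others kept it in fewer of 18 (and of 23 with 1 array left out): xylem and phloem in 7 minus 3 months 8 (13), photosynthesis in leaf FMO minus TYA 9 (11) and in 7 minus 3 months 10 (16), polyketide synthases in 7 minus 3 months 10 (17) and in 5 minus 3 months 11 (15), cytochrome P450s in root minus rhizome 11 (17), heat shock in 5 minus 3 months 11 (19), peroxidases in 7 minus 5 months 11 (19), xylem and phloem in variety by leaf 13 (18) and terpene synthases in variety by stage 14 (19). The rest kept it in 17 (22 or 23). No called list reversed.

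With 1 array left out at a time the counts ranged: leaf minus rhizome 3105 to 4108, root minus rhizome 788 to 1531, leaf minus root 2617 to 3620, 5 minus 3 months 72 to 1080, 7 minus 5 months 103 to 1279, 7 minus 3 months 381 to 977, rhizome FMO minus TYA 1987 to 2753, leaf FMO minus TYA 699 to 1476, root FMO minus TYA 201 to 500, variety by stage 18 to 46, variety by leaf 127 to 330, variety by root 3 to 92, rhizome-enriched 180 to 288 and list shifts 15 to 28. The arrays whose absence moved a count by more than 1.5 times are named as Cy3/Cy5, rhizomes by their month. For 7 minus 5 months (591 with all arrays): 362 without FMO 3/FMO 7, 1279 without FMO 5/FMO 7, 103 without FMO 5/TYA 7, 129 without FMO 7/TYA 5, 307 without TYA 7/TYA 5 and 342 without TYA 7/TYA 3. For 7 minus 3 months (909 with all arrays): 386 without FMO 3/FMO 7 and 381 without TYA 7/TYA 3. For 5 minus 3 months (604 with all arrays): 98 without TYA 5/FMO 3, 999 without FMO 5/FMO 7, 402 without FMO 5/TYA 7, 72 without TYA 3/FMO 5, 379 without FMO 7/TYA 5, 316 without TYA 7/TYA 3 and 1080 without TYA 5/TYA 3. For variety by stage (46 with all arrays): 24 without FMO 5/TYA 7, 21 without FMO 7/TYA 7, 23 without FMO 7/TYA 5, 24 without TYA 7/TYA 5, 18 without TYA 7/TYA 3, 21 without TYA 5/TYA 3, 22 without FMO root/FMO 7, 24 without TYA leaf/FMO leaf, 24 without TYA root/FMO leaf, 26 without TYA 7/TYA leaf and 25 without TYA 7/FMO 7. For root minus rhizome (1402 with all arrays): 864 without FMO root/FMO 7, 908 without FMO root/TYA 7 and 788 without FMO 7/TYA root. For root FMO minus TYA (480 with all arrays): 262 without FMO root/FMO 7, 300 without FMO root/TYA 7, 293 without TYA root/FMO leaf and 201 without FMO 7/TYA root. For variety by root (4 with all arrays): 11 without FMO leaf/FMO root and 92 without FMO 7/TYA root. For leaf FMO minus TYA (1404 with all arrays): 699 without TYA leaf/FMO leaf. For variety by leaf (296 with all arrays): 127 without TYA leaf/FMO leaf. For list shifts (24 with all arrays): 15 without FMO 5/FMO 7. The arrays of scan 1, with the lowest median signals, carry most of the 3-month channels. Whether the number of arrays that touch a group limited the calls was not tested.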

Other observations

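Further groups of genes, 9 lists chosen after the results were seen, were tested with camera over the 12 comparisons, and none was called with an estimated correlation. WRKY transcription factors, regulators of defence and stress responses, shifted up in root against rhizome, with 9 of 51 risen and 0 fallen (camera adjusted p = 0.00882, and adjusted p = 0.352 with an estimated correlation), among them WRKY3 (pGT1_07022_01, 2.10 ± 0.26) and WRKY33 (pGT1_10351_01). They also shifted up in the rhizome from 3 to 7 months, 6 and 0 (adjusted p = 0.0326, and adjusted p = 0.457 with an estimated correlation). Aquaporins, which carry water across membranes, were lower in leaf than in rhizome, with 1 of 40 risen and 16 fallen (adjusted p = 0.00882, and adjusted p = 0.352 with an estimated correlation), and lower in leaf than in root, 1 and 10 (adjusted p = 0.0326, and adjusted p = 0.457 with an estimated correlation), where ZmPIP1-4 was at -3.30 ± 0.21 (pGT1_00010_21). For variety by leaf they shifted down with 0 risen and 1 fallen (adjusted p = 0.0326, and adjusted p = 0.457 with an estimated correlation). Proteases were higher in leaf than in root, with 36 of 140 risen and 11 fallen (adjusted p = 0.0326, and adjusted p = 0.301 with an estimated correlation). Metallothioneins shifted down in the rhizome from 5 to 7 months, with 2 of 35 risen and 5 fallen (adjusted p = 0.0326, and adjusted p = 0.343 with an estimated correlation), and shifted down for variety by leaf with 0 and 1 (the same adjusted p in both).

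Probes described as terpenoid synthase, which are not in the terpene synthase list, shifted down for variety by stage with 0 of 10 risen and 1 fallen (adjusted p = 0.00145, and adjusted p = 0.343 with an estimated correlation). The fallen one, pGT1_10261_01, was higher in FMO in the rhizome (3.85 ± 0.36) and lower in leaf. An orcinol O-methyltransferase (pGT1_02179_01), of a class that makes scent compounds, was higher in FMO rhizome (4.01 ± 0.47). MYB factors (50 probes), O-methyltransferases (20), glutathione S-transferases (37) and the ubiquitin and proteasome list (221) were not called in any of the 12 comparisons.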
